A study of Mus musculus with 8 samples.

How the data were processed

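Chromatin immunoprecipitation followed by sequencing (ChIP-seq) with an antibody against trimethylated lysine 9 of histone H3 (H3K9me3) was carried out on frozen jejunum from 8 C57BL/6 mice, per the labels' protocols. The mice formed 4 groups of 2 mice, given by genotype and treatment in the labels: Msh2+/+ and Msh2-/- mice, each unirradiated or irradiated. Both Msh2 alleles were floxed in all 8 mice. Msh2-/- mice also carried a Cre recombinase under the villin promoter, which is active in intestinal epithelium. Msh2+/+ mice had no Cre. Irradiated mice received 0.5 Gy of X-rays at an age of 3 months. All mice were killed after 28 days.

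Per the labels' protocols, chromatin was sheared with SDS buffer and a Covaris kit, immunoprecipitation ran on an automated Diagenode system, and libraries were made either with a PCR-free or with a Nano TruSeq kit. Which mouse had which kit is not given in the sources used here. Sequencing was paired-end on an Illumina HiSeq instrument. Per the submitters' processing notes, cutadapt and MACS 1.4.2 were used, and mm9 is named among the builds beside GRCh37 and hg19, which are human. The aligner, the input control, the peak threshold and the distance within which a peak counts for a gene are not given in the sources used here.

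The authors deposited 2 tables of calls. The larger holds 31591 genes, 1 row per gene symbol, and the smaller holds 752 of them. Each value is 0 or 1, a call that a gene carries a modification in a group of mice or does not. It has no height, fold enrichment or peak position. How the peaks of 2 mice became 1 call per group is not given in the sources used here. The genes of the smaller table were those with an H3K9me3 call in at least 1 group of the larger, and 0 cells differed between the tables. Each table also holds 12 columns of calls for 3 other marks: H3K4me3, found at active promoters, H3K27me3, deposited by Polycomb complexes, and H3K36me3, found over transcribed gene bodies. The libraries behind these are not among the 8 samples, and the calls were used as the authors' values. The smaller table marks 17 genes as lying in greylisted regions, regions with abnormal signal in input DNA.

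Columns named Plus were read as Msh2+/+ and columns named Minus as Msh2-/-, after the symbols of the design text. If Plus stood for the presence of Cre, every difference between genotypes given here would be turned around. The calls hold nothing that could check this reading, because the deleted part of Msh2 cannot be seen in a call per gene.

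Sequencing depth per mouse is unknown from these tables, and no value per mouse was given, so that no spread between mice, no standard deviation and no test across mice could be computed. The tests across mice that were set out before the data were examined were therefore replaced by the comparison of call sets, which had been set out for the case of group-level calls. Differences between groups are counts of genes with no p-value. Gene lists, chromosomes, annotated types and other marks were tested with 2-sided Fisher exact tests over genes, all 31591 genes of the larger table serving as background, and adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Genes are not independent replicates, and neighbouring genes can share 1 region of signal. These were therefore also tested by rotating the calls along the gene order 9999 times, which keeps neighbours together, with a smallest possible p of 0.0002. Tests within the zinc finger list, on promoter and coding sequence and in the alternatives other than rotation used the Fisher exact test alone. Confidence intervals are at 95% and treat genes as independent. Intervals of shares are exact Clopper-Pearson intervals.

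On simulated data with lists of 200 genes among 31591 genes, the Fisher test called 4 of 100 lists with a true odds ratio of 1, 89 with a true odds ratio of 3 and 100 with a true odds ratio of 10, against calls in any group. The rotation test called 3, 88 and 100. Where calls and lists, here of 400 genes, were both laid out in runs of 20 neighbouring genes with no link between them, the Fisher test called 76 of 100 lists and the rotation test 3. The real calls were less clustered, with 421 of 523 merged loci holding 1 gene. The 76 is therefore not an estimate of false Fisher calls in these data.

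A total of 19 lists of gene symbols and 13 lists defined by symbol pattern were fixed before the data were examined. They covered chromatin and DNA repair machinery, intestinal cell types, other cell types of the gut wall, imprinted and germline genes, promoters hypermethylated in intestinal tumours, and multigene families. The list of Y chromosome genes had no member in the table, which holds 0 genes of chromosomes X, Y and M, so that 31 lists were tested. Older symbols were used for 12 list members. The genes named in the text were also fixed by rule: Msh2, the genes that differ between the groups compared and belong to a list, up to 5 per list in alphabetical order, and the first 10 other genes in alphabetical order. Clone names and symbols of the Gm, Rik, LOC, Mir and Snor type did not count as names. The paragraphs do not name every gene that the rule gave, and no rule fixed which were left out. Members of 5 lists (H3K9 methyltransferases and readers, columnar and reserve stem cell genes, mismatch repair and p53 targets) were to be named wherever called. Genes called in all 4 groups were named in the same order, which the rule did not provide for. Zinc finger genes of single loci and the genes that illustrate or prompted the last tests were named outside the rule.

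Coordinates are given in mm9 (NCBIM37), counted from 1. Of the genes, 31519 matched a transcript of GENCODE M1 (Ensembl 65) by identifier, with 94.6% at the same start and 100% on the same chromosome. The other 72 lay on unplaced contigs, and 0 of these were called. A set of 8 genes had an end before its start, 0 of them called, and these were left out wherever length was used. Called genes within 100 kb of each other were merged into a locus. Promoter sequence was read 500 bp to either side of the gene start, and coding sequences were searched for C2H2 zinc finger motifs and repeated words of 15 bases. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Alternatives were named symbols only, another background without zinc finger and olfactory receptor genes, and only genes present in both tables. Removal of greylisted genes, protein-coding genes only, removal of unplaced contigs, counting by locus, rotation and removal of a called locus on chromosome 9 were added after seeing the data.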

Results

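H3K9me3, a histone modification of constitutive heterochromatin, was mapped in jejunum of mice, unirradiated or 28 days after 0.5 Gy of X-rays. The mismatch repair gene Msh2 was intact, or was deleted by a Cre recombinase active in intestinal epithelium. Cells of the jejunum outside the epithelium are not the target of this Cre. Of 31591 genes, 752 (2.38%) carried an H3K9me3 call in at least 1 of the 4 groups and 30839 in none. Each group of 2 mice is represented by 1 call per gene, so that no error between mice can be given, and depth is unknown. Genotype labels rest on the reading of the column names described with the processing. Msh2 itself, at chromosome 17, 88071670 to 88123053 on the plus strand (mm9, ENSMUST00000024967), had no H3K9me3 call in any of the 4 groups and an H3K4me3 call in all 4. Its H3K36me3 call was present in irradiated Msh2+/+ and unirradiated Msh2-/- mice. These calls cover the whole gene and cannot show the conditional deletion.

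H3K9me3 calls were enriched at zinc finger genes, which encode DNA-binding proteins and lie in large clusters. Of 393 genes on the zinc finger list, 106 were called in at least 1 group, where 9.36 were expected. The odds ratio was 17.5 (95% confidence interval 13.8 to 22.2), with an adjusted p of 5.07e-79 in the 2-sided Fisher exact test and of 0.0031 in the rotation test, whose raw p of 0.0002 was the smallest it can give. The enrichment was present in all 4 groups. It comprised 77 genes in unirradiated Msh2+/+ mice (odds ratio 34.2), 69 in irradiated Msh2+/+ mice (31.1), 95 in unirradiated Msh2-/- mice (26.9) and 73 in irradiated Msh2-/- mice (23.4). Zfp110, Zfp111, Zfp119b, Zfp125 and Zfp146 were called in all 4 groups.

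The more groups shared a call, the more often the gene was a zinc finger gene. Zinc finger genes made up 0.931% of the genes never called, 4.38% of the 411 genes called in 1 group (exact interval 2.62 to 6.83), 11.2% of the 125 called in 2, 25.2% of the 111 called in 3 and 43.8% of the 105 called in all 4 (34.1 to 53.8). Genes outside the list that were called in all 4 groups included Ctse, which encodes cathepsin E, the mucin gene Muc19, the vomeronasal receptor gene Vmn1r48, the proton pump gene Atp6v1h, Cmc1, Coro2b and Fam73a. AI987944, AU041133, AW146154 and BC002059 belonged to the same set, but encode 9, 14, 12 and 9 C2H2 zinc finger motifs. The list goes by symbol and misses such genes.

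**Figure D1:**
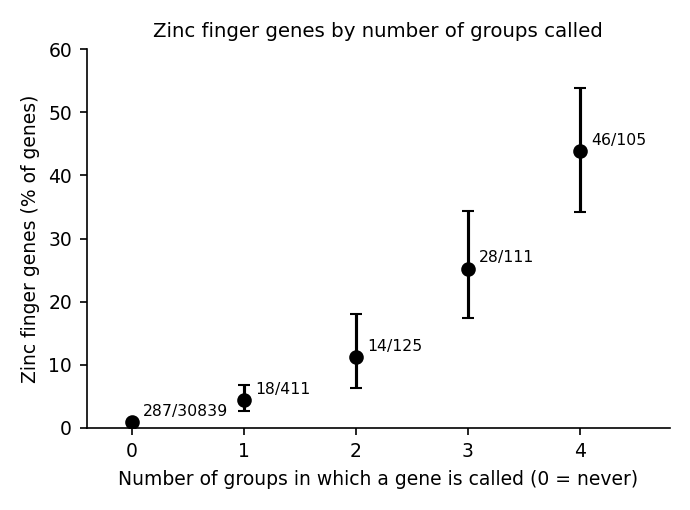
Share of zinc finger genes, in percent of genes, against the number of groups in which a gene carried an H3K9me3 call. Points are shares, bars are 95% exact binomial intervals that treat genes as independent, and the fractions give zinc finger genes over all genes; the share was 0.931% among genes never called and 43.8% among genes called in all 4 groups.

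Olfactory receptor genes, which also lie in large clusters and are mainly expressed in sensory tissue, were almost free of calls. Of 1239 such genes, 2 were called (Olfr119 in unirradiated Msh2+/+ mice, Olfr1388 in unirradiated Msh2-/- mice) where 29.5 were expected. The odds ratio was 0.0638 (0.0230 to 0.276), with an adjusted p of 8.9e-10 in the Fisher exact test and of 0.0031 in the rotation test. Neither test took gene length into account. Vomeronasal receptor genes were called at about the expected number, 10 of 324 against 7.71 (adjusted p of 1, Fisher exact test). Among cytochrome P450 genes 5 of 91 were called against 2.17 expected (adjusted p of 0.51, Fisher exact test).

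Lists of genes of the intestinal epithelium were mostly without calls. Among 12 goblet cell genes, 2 were called, both in unirradiated Msh2-/- mice alone. These were Clca1 (chromosome 3, 144392641 to 144423941) and Fcgbp (chromosome 7, 28856255 to 28905880), of which Fcgbp encodes a secreted component of mucus. Symbols are those of the older annotation, and whether its Clca1 is the goblet cell gene of that name was not checked. The list did not pass the threshold after adjustment (Fisher exact p of 0.0319, adjusted p of 0.33). Germline genes had 2 calls among 36 genes (Tdrd1 and Tdrd9, of the piRNA pathway), genes with promoters often hypermethylated in intestinal tumours 1 among 33 (Cdkn2a), clustered protocadherins 1 among 25 (Pcdhga11) and histone genes 1 among 70 (Hist1h4m). None of these 4 lists passed the threshold (adjusted p of 1 each, Fisher exact test).

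No member was called in the remaining 22 lists. These included H3K9 methyltransferases and readers (12 genes), H3K9 demethylases (9), DNA methylation machinery (14), H3K4 and H3K27 methylation machinery (15), mismatch repair (12), p53 targets and DNA damage response (23), columnar stem cell (17), reserve stem cell (10) and Wnt and Notch genes (24). Enterocyte (23 genes), Paneth cell (14), enteroendocrine and tuft cell (19), immune cell (17), enteric nervous system (9) and imprinted genes (38) had no called member either, and nor did the 15 genes of smooth muscle, fibroblasts and endothelium. The families without a call were Hox (39 genes), defensin (71), ribosomal protein (75), H2 histocompatibility (41), keratin and serpin genes (66). The expected number was at most 2.40 called genes in any of these lists, so that 0 was not distinguishable from it in a single list (adjusted p of 1 each, Fisher exact test).

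The number of genes with a call was compared between groups first. Unirradiated Msh2+/+ mice had 298 (0.943% of genes), irradiated Msh2+/+ mice 281 (0.889%), unirradiated Msh2-/- mice 461 (1.46%) and irradiated Msh2-/- mice 374 (1.18%). Counted as loci merged within 100 kb, these were 216, 204, 315 and 263. The share of calls found in no other group was 26.2% (78 genes) in unirradiated and 13.2% (37) in irradiated Msh2+/+ mice, against 36.2% (167) in unirradiated and 34.5% (129) in irradiated Msh2-/- mice. Any pair of groups shared between 29.2% and 40.2% of the genes called in either. These were 152 to 212 genes, where independent sets would share 2.65 to 5.46. Groups alike in genotype or irradiation did not always share more than groups that differed in both. Irradiated Msh2+/+ and unirradiated Msh2-/- mice shared 212 genes (40%), and unirradiated Msh2+/+ and irradiated Msh2-/- mice 152 (29.2%). The share was 40.2% between the Msh2+/+ groups, 33.4% between the Msh2-/- groups, 32.5% between the unirradiated and 33.1% between the irradiated groups. No p-value belongs to these differences, since each group gave 1 set of calls.

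**Figure D2:**
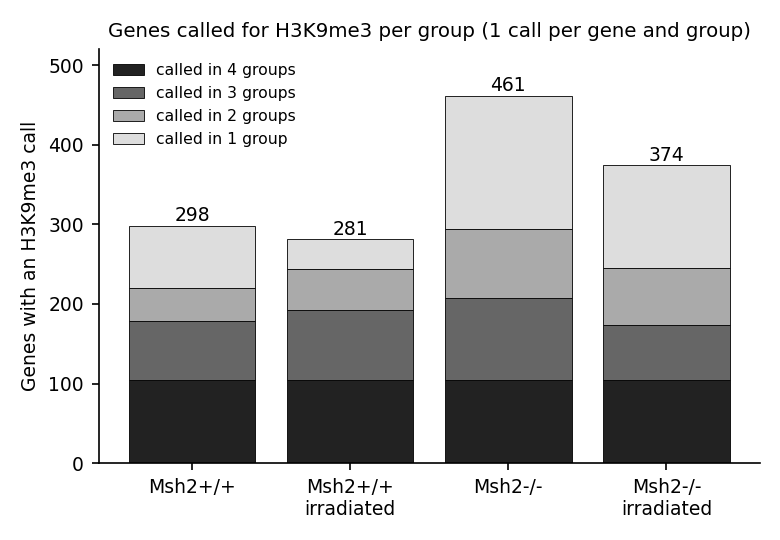
Number of genes with an H3K9me3 call in each of the 4 groups (1 call per gene and group, no replicate error), divided by the number of groups in which the gene was called. The bars stand at 298, 281, 461 and 374 genes, and 105 genes of each bar were called in all 4 groups.

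The unirradiated Msh2+/+ and Msh2-/- groups, which also differ in Cre, were compared. A total of 186 genes were called in both, 275 in Msh2-/- mice alone and 112 in Msh2+/+ mice alone, a ratio of 1.55 between the totals and of 1.46 between loci. Zinc finger genes made up 39.8% of the shared genes (74), 7.64% of those called in Msh2-/- mice alone (21, among them Zfp119a, Zfp167, Zfp184, Zfp192 and Zfp2) and 2.68% of those called in Msh2+/+ mice alone (Zfp113, Zfp442 and Zfp71-rs1). Besides Clca1, Fcgbp, Tdrd9 and Olfr1388, the genes called in Msh2-/- mice alone included Cyp2c54, Cyp4v3, the vomeronasal receptor genes Vmn1r126, Vmn2r39 and Vmn2r47, Pcdhga11, the peroxisomal oxidase gene Acox3, the transcription factor gene Batf3, Bst1, Ahnak2, Alg11, Amn1, Ankrd22, Apbb3, Atg2b and BC005561. Those called in Msh2+/+ mice alone included Tdrd1, Olfr119, Vmn2r45, Cyp2c38, Cyp2c68, the chemokine receptor gene Ccr5, the chitinase gene Chia, the liver and gut transcription factor gene Creb3l3, Bcar1, Cryz, Accn4, Adssl1, Atp6ap1l, Ccdc50 and Cenpo.

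Between the irradiated groups, 163 genes were called in both genotypes, 211 in Msh2-/- mice alone and 118 in Msh2+/+ mice alone, a ratio of 1.33 between the totals and of 1.29 between loci. Zinc finger genes were 24 of the 211 (11.4%; Zfp105, Zfp113, Zfp12, Zfp120 and Zfp189 among them) and 20 of the 118 (16.9%; Zfp119a, Zfp369, Zfp386, Zfp595 and Zfp606). Calls in Msh2-/- mice alone included Vmn2r46, Vmn2r47, Cyp2c54, Cyp2j13, the bile acid synthesis gene Akr1d1, the plasma protein genes Afm and Apoh, the glycogen debranching enzyme gene Agl, Adam4, Adam5, Arid4a and Atp6v1e1. Calls in Msh2+/+ mice alone included Tdrd1, Vmn1r158, Vmn2r11, Vmn2r97, the fatty acid oxidation gene Acaa2, Akr1c14, B4galnt2, Bzw2, Accn4 and Atg2b. Of the 211 genes, 13 lay side by side at the start of chromosome 9, in sequence that matched itself at a shift of 234 bp over 71.2% of bases.

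Both comparisons of genotypes gave the same side for 54 genes. Of these, 43 were called in both Msh2-/- groups and in neither Msh2+/+ group. They included 8 zinc finger genes (Zfp192, Zfp316, Zfp334, Zfp534 and Zfp869 first in the alphabet), Cyp2c54 and Vmn2r47, the metallothionein gene Mt1 (chromosome 8, 96702989 to 96704225), the cadherin gene Fat1 (chromosome 8, 46035562 to 46137611), the helicase gene Helb, the coactivator gene Eya2, Crlf2, Klrb1a, Grin3b, Ccdc79, Gtpbp6 and the potassium channel gene Kcnk12. The other 11 were called in both Msh2+/+ groups alone and held 0 zinc finger genes. They included Tdrd1 (chromosome 19, 56900765 to 56944502), the ion channel gene Accn4, the centromere protein gene Cenpo, the phosphate transporter gene Slc20a2, Ccdc50, Ppa2 and Trim5.

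The effect of irradiation was examined within each genotype, 28 days after exposure. In Msh2+/+ mice 166 genes were called with and without irradiation, 115 after irradiation alone and 132 without irradiation alone, and the total was 0.943 times that of unirradiated mice. Zinc finger genes made up 36.7% of the shared genes, 6.96% of those called after irradiation alone (8, among them Zfp119a, Zfp2, Zfp422-rs1, Zfp612 and Zfp850) and 12.1% of those called without irradiation alone (16, among them Zfp113, Zfp12, Zfp120, Zfp189 and Zfp40). Calls after irradiation alone included the tumour suppressor gene Cdkn2a, Hist1h4m, 4 vomeronasal receptor genes (Vmn1r158, Vmn2r11, Vmn2r55 and Vmn2r97), Acaa2, Akr1c14, Bst1 and Bzw2. Calls without irradiation alone included both P450 genes called in this group (Cyp2c38 and Cyp2c68), Olfr119, Vmn2r45, the fatty acid oxidation gene Acadl, Bcar1, Ccr5, Cd163l1, Chia and Creb3l3.

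In Msh2-/- mice 209 genes were called with and without irradiation, 165 after irradiation alone and 252 without irradiation alone, and the total was 0.811 times that of unirradiated mice. Zinc finger genes made up 32.1% of the shared genes, 3.64% of those called after irradiation alone (6, among them Zfp105, Zfp113, Zfp28, Zfp706 and Zfp790) and 11.1% of those called without irradiation alone (28, among them Zfp119a, Zfp167, Zfp184, Zfp248 and Zfp260). Calls after irradiation alone included Cdkn2a, Hist1h4m, Vmn2r46, Vmn2r55, Cyp2j13, Akr1d1, Afm, Apoh, Agl and the 13 neighbouring genes on chromosome 9. Calls without irradiation alone included Clca1, Fcgbp, Tdrd9, Pcdhga11, Cyp4v3, Acadl, Acox3, B4galnt2 and Batf3.

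Irradiation gave the same side in both genotypes for 28 genes, fewer than the 54 for genotype. The 13 genes called in both irradiated groups alone were 0 zinc finger genes and included Cdkn2a (chromosome 4, 88920377 to 88940523, minus strand), Hist1h4m, Vmn2r55, the Golgi protein gene Golga3, Pag1, Pxt1 and Trim14. By locus, not all of these were confined to irradiated mice. Gm12606, in the same merged locus as Cdkn2a, was called in unirradiated Msh2+/+ mice, and the locus of Golga3 had calls in every group. The 15 genes called in both unirradiated groups alone included Zfp40, Zfp72, Zfp788, Acadl, D3Ertd254e, the RNA helicase gene Eif4a3, Kalrn, Pigt and Stk19. The sides were opposite in the genotypes for 43 genes. Of these, 28 were called in irradiated Msh2+/+ and unirradiated Msh2-/- mice alone, including Zfp119a, Zfp953, the autophagy genes Atg2b and Pik3c3, Hnmt, Il3ra, the telomere protein gene Pot1b, Bzw2, Ccdc15, Cep57l1, Lcorl and Mtap6. The other 15, called in unirradiated Msh2+/+ and irradiated Msh2-/- mice alone, included Zfp113, the oocyte homeobox genes Obox1 and Obox2, Kif27 and Rbm12b. The difference between the counts of 28, 43 and 54 was not tested.

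Calls per chromosome departed from expectation past the threshold only in the Fisher exact test, which treats genes as independent. Chromosome 13 held 69 called genes against 29.8 expected (odds ratio 2.54, adjusted p of 2.36e-09, Fisher exact test), and chromosomes 7, 12 and 17 also passed the threshold above expectation (97, 46 and 50 genes, odds ratios 1.57, 1.71 and 1.47). Chromosomes 15, 11, 14 and 6 passed it below expectation, with 4, 35, 16 and 24 genes and odds ratios of 0.162, 0.501, 0.429 and 0.557. Without the genes of the zinc finger list, chromosome 17 held 29 genes against 29.5 expected. Chromosome 6 then no longer passed (odds ratio 0.623, adjusted p of 0.0642, Fisher exact test), while chromosomes 7, 11, 12, 13, 14 and 15 did. The list goes by symbol, so 46 called genes with at least 3 C2H2 zinc finger motifs under other symbols stayed in. What they add to the chromosomes that still passed was not tested. With named symbols only or protein-coding genes only, chromosomes 6, 7 and 12 no longer passed the threshold. In the rotation test, which keeps runs of neighbouring calls together, no chromosome passed the threshold in either direction (adjusted p of at least 0.825, and of at least 0.969 without the genes of the zinc finger list). A chromosome is itself a single long run of genes, so small rotations hardly change its overlap and this test can hardly pass. Whether calls differ between chromosomes beyond their clustering therefore cannot be told.

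The 752 genes formed 523 loci, 421 of them of 1 gene, and 14 loci held 5 or more. The locus with most called genes lay on chromosome 4 (146316585 to 147222475) with 14 called genes, 3 in unirradiated and 2 in irradiated Msh2+/+ mice, and 9 in unirradiated and 10 in irradiated Msh2-/- mice. A locus on chromosome 10 (81111816 to 81704018) held 12 called genes, including Zfp781, Zfp873 and Zfp938, with 9, 11, 12 and 8 in the same order of groups. On chromosome 13 (67572450 to 67944050), 11 of 17 genes were called, with 10, 6, 9 and 7 in that order. Among these, 6 genes, such as Zfp58, Zfp738 and Zfp71-rs1, belonged to the zinc finger list.

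**Figure D3:**
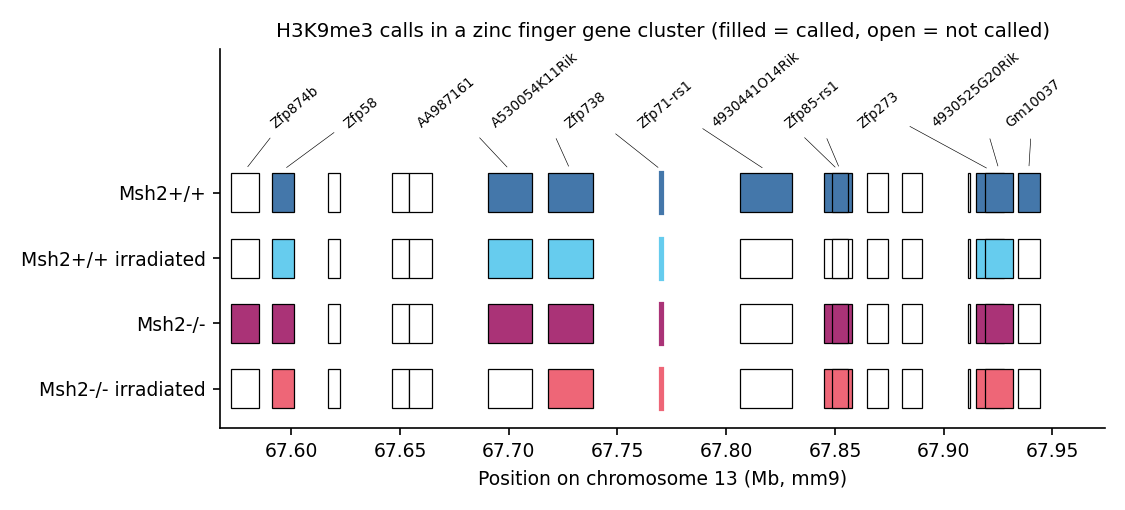
H3K9me3 calls in a zinc finger gene cluster on chromosome 13, 67572450 to 67944050 (mm9). Boxes are gene bodies drawn to scale in Mb, filled where the gene was called in the group of that row and open where it was not, and overlapping genes share space; symbols name the 11 called genes of 17. Gene bodies are shown because the calls carry no peak positions.

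By annotated type, 549 of 21275 protein-coding genes were called (odds ratio 1.32, adjusted p of 0.0035 in the Fisher exact test and 0.045 in the rotation test). All 106 called zinc finger genes are among them, and outside the list 443 of 20887 were called (odds ratio 1.08, adjusted p of 0.68, Fisher exact test). Pseudogenes were at 118 of 4028 (odds ratio 1.28, adjusted p of 0.052, Fisher exact test). Outside the list their odds ratio was 1.52 (adjusted p of 0.000646 in the Fisher exact test and 0.024 in the rotation test). Long intergenic RNA genes were at 30 of 1225 (1.03, adjusted p of 1). MicroRNA genes were below, 9 of 1461 (0.245, adjusted p of 3.45e-06), and none of 299 small nucleolar RNA genes was called (adjusted p of 0.0061, Fisher exact test). Both passed the rotation test (adjusted p of 0.003 and 0.0165). Called genes had a median length of 14.4 kb and never-called genes of 6.73 kb. Neither test took gene length into account, so what the shortness of such RNA genes adds to these depletions was not tested. None of 355 immunoglobulin variable segments was called either, which passed in the Fisher exact test (adjusted p of 0.0024) but not in the rotation test (0.0653).

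H3K9me3 calls were next compared with the other modifications. Genes with H3K9me3 more often carried H3K36me3, the mark of transcribed gene bodies, in all 4 groups. H3K36me3 itself was called at 1954 genes in unirradiated Msh2+/+ mice and at 9881 to 10863 in the other groups. In unirradiated Msh2+/+ mice, 22.5% of H3K9me3 genes had it against 6.03% of the others (odds ratio 4.52, adjusted p of 1.74e-19, Fisher exact test). The shares were 47.3% against 31.1% in irradiated Msh2+/+ mice (odds ratio 1.99), 47.9% against 34.2% in unirradiated Msh2-/- mice (1.77) and 43.3% against 31.5% in irradiated Msh2-/- mice (1.66). All 4 adjusted p were at most 7.07e-06 in the Fisher exact test and 0.0024 in the rotation test. With only the 752 genes of both tables as background, irradiated Msh2-/- mice no longer passed (odds ratio 1.34, adjusted p of 0.0904, Fisher exact test). Each of these genes has an H3K9me3 call in some group, so that this compares H3K9me3 genes of 1 group with those of the others and does not bear on the link itself. Within the zinc finger list the odds ratios were 7.31, 4.54, 6.02 and 6.46 in the same order. Outside the list the odds ratio was 2.95 in unirradiated Msh2+/+ mice and at most 1.16 in the other groups, where it did not pass the threshold. The 2.95 rests on 35 genes with both marks and on the small H3K36me3 set of 1954 genes. It is therefore not directly comparable with the other groups. Zinc finger genes under other symbols also remain outside the list. Of the 106 called zinc finger genes, 93.4% had H3K36me3 in at least 1 condition, compared with 72.1% of the 287 never called.

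H3K27me3, the Polycomb mark, was less frequent at H3K9me3 genes over all genes. The odds ratios were 0.573 in unirradiated and 0.379 in irradiated Msh2+/+ mice, and 0.599 in unirradiated and 0.535 in irradiated Msh2-/- mice (adjusted p of 0.0295, 0.000619, 0.00823 and 0.0031, Fisher exact test). In unirradiated Msh2+/+ mice the call ended in the rotation test (adjusted p of 0.0522), and in unirradiated Msh2-/- mice with named symbols only (odds ratio 0.659, adjusted p of 0.103, Fisher exact test). Among the 752 genes, where again only H3K9me3 genes of different groups are compared, unirradiated Msh2+/+ and irradiated Msh2-/- mice did not pass (0.665 and 0.775, adjusted p of 0.25 and 0.409, Fisher exact test). Outside the zinc finger list the odds ratios were 0.739, 0.418, 0.738 and 0.643, and only that of irradiated Msh2+/+ mice passed the threshold (adjusted p of 0.0113 in the Fisher exact test and 0.02 in the rotation test). H3K4me3, the mark of active promoters, was found at 44.9% to 48.0% of H3K9me3 genes. The odds ratios of 1.01, 0.855, 0.832 and 0.875 did not pass the threshold. Outside the zinc finger list they were 0.781, 0.677, 0.654 and 0.712, and the last 3 passed it in the Fisher exact test (adjusted p of 0.0137, 0.000458 and 0.0113), but in the rotation test only that of unirradiated Msh2-/- mice did (0.0156). Among protein-coding genes alone they were 0.723, 0.719, 0.743 and 0.739, all past it (adjusted p of 0.0166, 0.0202, 0.0122 and 0.0166, Fisher exact test, no rotation test run). Calls per gene do not show whether 2 marks lay on the same part of the gene or in the same cells.

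**Figure D4:**
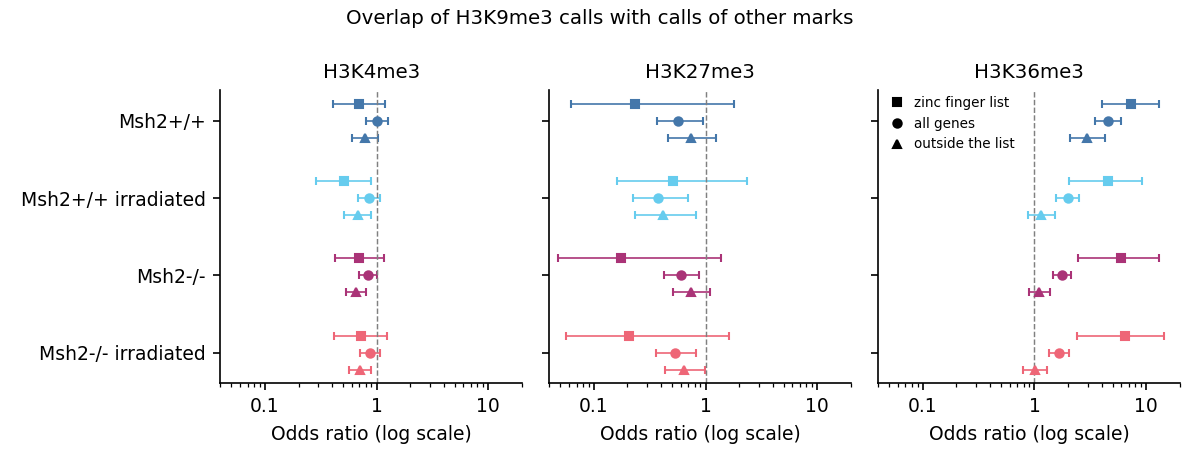
Odds ratios (log scale, with 95% intervals that treat genes as independent) of carrying H3K4me3, H3K27me3 or H3K36me3 for genes with an H3K9me3 call against genes without, per group. Squares are genes of the zinc finger list, circles all genes and triangles genes outside the list; for H3K36me3 the odds ratios are 4.54 to 7.31 within the list and at most 2.95 outside it.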

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

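The test of peak-calling sensitivity by the share of common calls was chosen only after the result was seen.

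H3K36me3 calls were singled out because they moved in opposite directions in the genotypes. Irradiated minus unirradiated mice differed by 7927 genes in Msh2+/+ mice and by -853 genes in Msh2-/- mice. The difference was not tested, as each condition has 1 set of calls, and it rests on unirradiated Msh2+/+ mice, with 1954 genes against 9881, 10863 and 10010 in the other 3 conditions. A lower sensitivity of that profile predicts that its genes are a subset of the others', and 98.2% of them were also called in at least 2 of the other 3 conditions. H3K4me3 (14726 genes) and H3K27me3 (3176 genes) also had their fewest calls in this condition, though they were not reduced to a like degree. Genes with H3K4me3 in all conditions but this numbered 702, against 29, 40 and 48 for the other conditions. For H3K27me3 they numbered 243, against 155, 182 and 60. A weak H3K36me3 immunoprecipitation may account for the pattern, but a milder shortfall of these marks goes with it. A real loss of H3K36me3 would leave a subset as well, and an effect of genotype and irradiation stays open.

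Pseudogenes with H3K9me3 were singled out by the same criterion, with 13 more in irradiated than in unirradiated Msh2+/+ mice and a difference of -26 in Msh2-/- mice, and the difference was not tested. Long intergenic RNA genes with H3K9me3 differed by 1 in Msh2+/+ mice and by -4 in Msh2-/- mice, also untested.

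More genes carried H3K9me3 in Msh2-/- than in Msh2+/+ mice, with or without irradiation. Gene-dense domains counted once per gene do not account for it, because the ratio of merged loci was still 1.29 in its lower case. Nor do calls that all fell on genes by chance in proportion to their length. The 275 genes called in unirradiated Msh2-/- mice alone had a median length of 13.2 kb, where such draws gave 84.1 to 125 kb. Only this extreme was tested, so chance falls of a part of the calls, or on gene starts alone, are not excluded. A difference in depth or peak-calling sensitivity cannot be told apart from an effect of Msh2 loss. Only Msh2-/- mice carried Cre, so an effect of Cre itself cannot be told apart either, and which mouse had which library kit is not known. Of the unirradiated Msh2+/+ calls, 62.4% were also called in unirradiated Msh2-/- mice, too few for a plain subset and too many to exclude a common ranking with noise near the threshold, and depth is unknown.

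A run of 13 neighbouring genes at chromosome 9, 3000922 to 3038316, was called in irradiated Msh2-/- mice and in no other group. Reads that cannot be placed within tandem repeats may be the source, but only the repetition was measured, not whether reads can be placed there. The region matched itself at a shift of 234 bp over 71.2% of bases, where a region of the same length on the same chromosome reached 28.3%, and 0 of the 13 genes are on the authors' greylist. Without them irradiated Msh2-/- mice had 361 calls, 116 of them in no other group. An increase of H3K9me3 on this repeat in irradiated Msh2-/- mice stays open, as 1 set of calls cannot separate it from a difference in input or mapping.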

How the results depend on the processing

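Alternatives chosen after seeing the data were removal of greylisted genes, protein-coding genes only, removal of unplaced contigs, counting by locus, rotation along gene order and removal of the chromosome 9 locus. No paired analysis was possible because the tables give 1 call per group, and the labels do not say which mice share a litter. For the same reason leaving out mice, other normalizations, pseudocounts, filters on low values, other model fits, other thresholds, calls per mouse and camera were not run. Each symbol has 1 row and no gene lies on X, Y or M, so alternatives on these change nothing. Depth is unknown, and what it limits cannot be stated. All 84 results compared were the same without unplaced contigs and without the chromosome 9 locus. The same held for 83 without greylisted genes, for 18 of 18 counted by locus, and for 55 of 66 by rotation. Rotation left H3K27me3 in unirradiated Msh2+/+ mice at an odds ratio of 0.573 with an adjusted p of 0.0522, and 0 chromosomes above and 0 below expectation, where the Fisher exact test gave 4 and 4. For whole chromosomes, rotation can hardly pass the threshold. For calls in any group, the zinc finger enrichment and the olfactory receptor depletion were the same with named symbols, protein-coding genes and rotation, and without greylisted genes, contigs or the chromosome 9 locus. In unirradiated Msh2+/+ mice alone the olfactory depletion passed in the Fisher exact test (adjusted p of 0.00211) but not by rotation (0.155). With a background without both families, their own lists could not be tested, and of the other lists 0 were above and 0 below expectation.

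With named symbols only, which removes genes, 178, 166, 246 and 193 genes were called in unirradiated and irradiated Msh2+/+ and unirradiated and irradiated Msh2-/- mice. Genotype gave 28 genes in both Msh2-/- groups and 7 in both Msh2+/+ groups alone, irradiation 7 in both irradiated and 9 in both unirradiated groups alone, and opposite sides 14 and 5. After irradiation alone there were 63 genes in Msh2+/+ and 74 in Msh2-/- mice, and without it 75 and 127. Msh2-/- mice alone had 136 genes unirradiated and 100 irradiated, Msh2+/+ mice alone 68 and 73. There were 2 chromosomes above expectation, and H3K27me3 in unirradiated Msh2-/- mice lost its call (odds ratio 0.659, adjusted p of 0.103).

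With protein-coding genes only, opposite sides held 17 and 9 genes, Msh2+/+ mice had 74 after irradiation alone, unirradiated Msh2-/- mice 176 alone, and 2 chromosomes were above expectation, again with fewer genes counted. The H3K4me3 odds ratio in unirradiated Msh2+/+ mice reversed from 1.01 to 0.723, and those of 0.719, 0.743 and 0.739 in the other groups passed the threshold. The cause was not tested. With only the 752 genes of both tables as background, H3K27me3 in unirradiated Msh2+/+ (0.665) and irradiated Msh2-/- mice (0.775) and H3K36me3 in irradiated Msh2-/- mice (1.34) no longer passed, with fewer genes tested. All 752 are called in some group, so this does not test the link of the marks with H3K9me3.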

Other observations

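The test of the Msh2 neighbourhood was chosen only after its result was seen, as were the tests of repeated sequence with genes set aside. The lists set out for other marks and the Hox clusters were picked after their values were seen.

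Counts of other marks at some of the fixed lists follow, none of them tested. Over all genes, H3K4me3 was called at 46.6%, 51.9%, 49.4% and 49.8% and H3K27me3 at 10.1%, 10.5%, 10.7% and 11.8%, in unirradiated and irradiated Msh2+/+ and unirradiated and irradiated Msh2-/- mice. All 23 enterocyte genes carried H3K4me3 in each of the 4 conditions, as did the 12 H3K9 methyltransferase and reader genes, while Paneth cell genes had H3K4me3 at 1, 0, 1 and 2 of 14 genes in the same order. Columnar stem cell genes carried H3K4me3 at 16, 17, 16 and 16 of 17 genes and H3K27me3 at 5, 4, 6 and 5. Promoters often hypermethylated in tumours carried H3K27me3 at 19, 20, 21 and 20 of 33 genes, and Wnt and Notch genes at 12, 11, 13 and 12 of 24.

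H3K27me3 was called at 23 of 39 Hox genes in unirradiated Msh2-/- mice, against 5 and 4 in unirradiated and irradiated Msh2+/+ mice and 2 in irradiated Msh2-/- mice. The calls lay in all 4 clusters, with 8 of 11 genes on chromosome 6 (52105594 to 52210796), 9 of 10 on chromosome 11, 5 of 9 on chromosome 2 and 1 of 9 on chromosome 15. Of the 248 genes with H3K27me3 in this condition alone, 18 were Hox genes, where the other 3 conditions had 1, 0 and 0 among 131, 169 and 300. H3K4me3 at Hox genes was called at 19, 27, 25 and 29, in the order used above. The difference has no replicate check and was not tested.

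The gene next to Msh2 followed the genotype. Kcnk12 (chromosome 17, 88145177 to 88197334, minus strand) lies 22.1 kb beyond the 3' end of Msh2, its own 3' end facing it, and was called for H3K9me3 in both Msh2-/- groups and in neither Msh2+/+ group. Epcam on the other side of Msh2, and Msh6 and Fbxo11 beyond Kcnk12, had no call. Kcnk12 carried H3K27me3 and H3K4me3 in all 4 conditions. A gene with this pattern lay as near to 61 of all genes (0.193%), which is rare, but Kcnk12 was picked after its calls were seen. Chance and an effect of the recombined Msh2 allele on nearby chromatin therefore cannot be told apart, and the latter may be worth a look in the reads.

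It was hypothesised that calls outside the zinc finger list also fall on zinc finger genes that go by other symbols. Among protein-coding genes outside the list, 46 of 439 called genes (10.5%) encoded at least 3 C2H2 motifs, against 0.947% of never-called genes (odds ratio 12.2, p of 8.86e-31, Fisher exact test), in line with the hypothesis. Examples are Rbak, AI987944, AU041133 and 2610008E11Rik, each called in all 4 groups. Over all protein-coding genes with a coding sequence, the share with at least 3 motifs was 7.99%, 23.0%, 48.8% and 68.2% for genes called in 1, 2, 3 and 4 groups, and 2.04% for genes never called. Called genes of the list had a median of 11 motifs and never-called ones 7.

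It was hypothesised that calls favour genes whose coding sequence repeats itself, as in the filaggrin gene Flg, Flg2, the hornerin gene Hrnr and Muc19. Among coding genes outside the list with fewer than 3 C2H2 motifs, 24 of 393 called genes were among the 1% with the highest share of repeated words, against 0.901% of never-called genes (odds ratio 7.15, p of 1.56e-12, Fisher exact test). Matching on coding length gave an expected 4.09 genes and a permutation p of 0.0002, the smallest the permutations can give. However, 12 of the 24 genes belong to the chromosome 9 repeat, without which the odds ratio was 3.58 (p of 0.00028, Fisher exact test). Another 4 encode 2 C2H2 motifs, and 4 are the genes that prompted the hypothesis, which are also the only named symbols among the 24. With all of these and other genes with a motif set aside, 4 of 370 called genes remained (1.08% against 0.906% of never-called genes, p of 0.582, Fisher exact test), so whether calls favour repeated coding sequence in general cannot be told.

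Calls were also hypothesised to favour CpG-rich gene starts, given the link of this series to promoter hypermethylation, and the data went the other way. Outside the zinc finger list, 32.1% of called protein-coding genes had a CpG-rich start against 44.9% of never-called genes (odds ratio 0.579, p of 5.45e-08, Fisher exact test), and the odds ratio was under 1 in each of the 4 groups.

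A last hypothesis was that calls found in unirradiated Msh2-/- mice alone extend from domains already called in Msh2+/+ mice. Of these 275 genes, 22.2% lay within 100 kb of an Msh2+/+ call, above the 4.41% of random genes from the same chromosomes. The mirrored share, of genes called in Msh2+/+ mice alone near an Msh2-/- call, was 16.1%, also above its random 5.66%. The excess was not over the 10 percentage points set in advance, so calls cluster in both directions and spreading in Msh2-/- mice in particular was not shown.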
